A study of Mus musculus with 36 samples.

How the data were processed

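Gene expression was measured on 36 MouseWG-6 v2 bead arrays of brown fat, inguinal fat and liver from male C57BL/6 mice aged 5 or 24 months. Each array carried 1 tissue, 1 age and 1 of 6 harvest times, 0 to 20 h at intervals of 4 h as in the sample titles; the treatment protocol gives 3 h. The design text names inguinal fat as dissected but epididymal fat at RNA isolation, and counts fewer mice than 3 per age and time would make; the sample labels were followed. The labels name 3 mice per array but do not say whether RNA was pooled or taken from 1 animal, so the p-values measure only the spread between these arrays.

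The deposited value table holds intensity per probe on a linear scale, and the authors name BeadStudio as the software, with no version given. Column medians lay between 11.8 and 12.1 and 33.8% of the values were below 0, as in background-subtracted, quantile-normalised data over all arrays. Whether further scaling preceded that step is not given in the sources used here, nor is the filter or annotation build. The 144 columns of the deposited scanner table carry names that no label holds and were tied to no sample, so the value table replaced the planned scanner table throughout. For this reason no background correction, median scaling and the beadchip as a block could not be tried. Arrays give no counts or depths, and the number of arrays limits the precision. Per array, 42.5% to 42.7% of the probes exceeded the detection minimum described next.

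Background was modelled with limma's normexp convolution on the deposited intensity, 16 was added, and values were transformed to log2. The spread of the values below 0 gave a noise SD of 9.38 intensity units, and a detection minimum of 21.8 at a one-sided p of 0.01. A probe was kept in a tissue when it exceeded that minimum in at least 6 of 12 arrays, and the brightest kept probe stood for its gene. Of 45281 probes, 34885 named 1 gene, 18 named several and 10378 none; the last 2 kinds were left out of the main comparisons. The named probes covered 19057 genes.

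R 4.3.3 and limma 3.58.1 (lmFit and eBayes) were used, with Benjamini-Hochberg adjustment and a threshold of 0.05. Age was tested in each tissue as old minus young with harvest time as a 6-level factor, so arrays were paired by the labelled time of harvest. Pairing was checked by correlating, across genes, young and old arrays of the same time after centring each gene on its age mean, which gave values from -0.34 to 0.41. Genes are not independent replicates, and a model without the time term was run as an alternative. Rhythm was tested with an F test of the cosine and sine of a 24 h period, with age in the model. The difference of rhythm between ages was tested with an F test of the age by cosine and age by sine terms. Age effects in a pair of tissues were compared by fitting age and time to the differences between their arrays of the same age and time. The level in brown fat was compared with that in inguinal fat on the 12 paired differences. Amplitude of the clock genes was compared between ages with an exact two-sided permutation test over all 64 swaps of the age labels within times, whose smallest p is 0.0312.

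Gene lists for pathways and cell types were written before the data were examined, as were the named-gene rule and the comparisons. They held 411 entries, of which 366 had a probe; entries without a probe were not analysed here. Each list with at least 3 tested genes was compared with all other genes by limma's camera at a preset correlation of 0.01, and again with an estimated correlation. Named genes are, per tissue, up to 12 genes that rose and 12 that fell with the largest change, past the threshold and with 1 direction at all 6 times. They also include the 10 largest amplitudes among rhythmic genes and all measured clock genes. For the difference of rhythm between ages the 5 genes with the smallest p are named, for each pair of tissues the 5 largest differences, and for the fat depots the 10 largest each way. Of every other list, the members past the threshold and up to 4 with the largest absolute change could be named. For a gene undetected in all 6 arrays of an age, or with its mean there below the detection minimum, "at least N-fold" sets the mean of the other age against that of the values raised to the minimum. The levels of the 2 fat depots were treated alike.

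The fits were tested on simulated data with independent normal noise for each gene, at the spread left by the age fit of each tissue or pair. For age, changes of 0.5, 1 and 2 on the log2 scale were recovered in 26.9%, 82.1% and 98.5% of the altered genes in brown fat. The shares were 28.4%, 70.1% and 93.9% in inguinal fat and 46.3%, 85.1% and 100% in liver. Rhythms with these amplitudes were recovered in 64.2%, 92.5% and 100% of genes in brown fat. The corresponding shares were 58.2%, 92.5% and 95.5% in inguinal fat and 73.1%, 98.5% and 100% in liver. Rhythms present in old arrays alone were recovered in 0%, 52.2% and 90.9% of genes in brown fat. They reached 1.5%, 47.8% and 81.8% in inguinal fat and 9.0%, 68.7% and 93.9% in liver. Differences of age effect between brown and inguinal fat were recovered in 6.0%, 53.7% and 95.5% of genes. For brown fat and liver the shares were 13.4%, 74.6% and 97.0%, and for inguinal fat and liver 11.9%, 65.7% and 90.9%. Each of these fits made between 3 and 12 false calls. The simulations held no correlation between genes, such as shared muscle or lymphocyte content would give. For rhythm, the 6 time levels had already been removed from the spread, which makes the noise too small. The shares and false calls may therefore not carry over to the real arrays.

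Alternatives covered the filter, the offset, the handling of low values, cyclic loess, probe averaging, eBayes with trend and robust settings, the time term, each array left out in turn, and muscle and lymphocyte content. RefSeq annotation on GRCm38.p6 was used only for gene names and for which genes neighbour each other.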

Results

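The samples were brown fat, inguinal fat and liver of male mice aged 5 months (young) or 24 months (old), taken at 6 times over a day under constant dim red light. Each age in each tissue held 6 arrays, 1 per harvest time, and the series held 36. The title of the series names the biology of ageing and circadian mechanisms as its subject, so age, daily rhythm and their combination are compared below. Differences are on the log2 scale, old minus young, each with its standard error from limma and n = 6 arrays per age, unless stated otherwise.

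The fat depots were compared first, as a measure of their identity. Ucp1, the uncoupling protein of brown fat mitochondria, was higher in brown than in inguinal fat by 8.99 ± 0.21 on the log2 scale, or 508-fold (n = 12 paired differences, adjusted p = 2.53e-08; detected in 4 of 12 inguinal arrays). Acot11, a thioesterase also expressed in brown fat, was 90.4-fold higher (adjusted p = 6.69e-09), the fatty acid transporter Slc27a2, detected in 3 of 12 inguinal arrays, at least 55.7-fold (adjusted p = 6.69e-09), and the kininogen gene Kng2 72.5-fold, with Kng1 also among the 10 largest. Fabp3, a fatty acid binding protein of muscle and brown fat, was higher by 7.03 ± 0.63. Muscle contractile genes were also higher in brown fat, with Myl2 at 6.84 ± 0.64, Myl3 at 6.29 ± 0.60 (detected in 5 and 4 of 12 inguinal arrays) and Tnnt1 at 5.91 ± 0.51. The mean log2 level of the skeletal muscle list was 11.83 ± 0.41 (SD, n = 6) in young brown fat and 8.59 ± 1.88 in young inguinal fat. The brown fat transcript Lncbate10 was detected in 12 of 12 brown arrays and 0 of 12 inguinal arrays.

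Inguinal fat was higher for Hoxc9, a homeobox gene of posterior body position, which was detected in 12 of 12 inguinal arrays and 0 of 12 brown arrays. Among the genes higher in inguinal fat, Fcmr, the Fc receptor for IgM, differed by -5.87 ± 0.37, the T cell receptor segment Trbv13-2 by -5.09 ± 0.35, the chemokine Ccl5 by -4.99 ± 0.31 and the B cell receptor component Cd79b by -4.79 ± 0.31. Il4i1, Ccl19 and Cd3d differed by between -4.98 and -4.44. H2-M2 and Ccr6, detected in 2 and 1 of 12 brown arrays, were at least 24.5-fold and 16.9-fold higher in inguinal fat. Fcmr, Trbv13-2, Il4i1 and Cd3d were detected in 6, 7, 6 and 5 of 12 brown arrays. Of 11338 genes tested, 4273 were higher in brown fat and 4554 higher in inguinal fat.

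In liver the largest age difference was in Cidea, a protein of lipid droplets that is abundant in brown fat. It rose by 4.51 ± 0.17, or 22.8-fold, and was higher in old liver at 6 of 6 times (adjusted p = 2.23e-05; detected in 5 of 6 young arrays). Its relative Cidec, also a lipid droplet protein, rose 6.90-fold (2.79 ± 0.20, 6 of 6 times, adjusted p = 0.00136), and Cyp2b9, a cytochrome P450 expressed mainly in female liver, at least 4.96-fold (6 of 6 times, adjusted p = 0.00136; detected in 2 of 6 young arrays). Genes of immune cells rose beside them, among them Gpnmb (at least 4.49-fold, detected in 1 of 6 young arrays), a glycoprotein of macrophage lysosomes, Ms4a7 (4.45-fold), a macrophage membrane protein, and Cxcl13 (5.71-fold), a chemokine that attracts B cells. In all, 335 genes rose and 60 fell of 10521 tested, and 386 of these 395 had the same sign at all 6 times. At an unadjusted p under 0.05 there were 1928 genes.

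The other genes of large rise were Ccl4, Ccl5, S100a8, Tmem45b, H2-M2 and Mzb1. Ccl4, a chemokine, was undetected in young liver and at least 4.21-fold higher in old liver (adjusted p = 0.0102), and the class I histocompatibility gene H2-M2 was at least 3.63-fold higher (adjusted p = 0.0474). Ccl5 rose 4.54-fold, S100a8, a calcium-binding protein of neutrophils that was detected in 5 of 6 young arrays, 4.62-fold. Tmem45b and Mzb1, a chaperone of plasma cells, were each detected in 1 of 6 young arrays and rose at least 3.55-fold and 3.21-fold. At 4 h the old array held 11.08 log2 of Ccl5 and 9.77 of H2-M2, each above the other 5 old arrays, whose highest were 8.95 and 7.32, and H2-M2 differed by -0.175 with lymphocyte content in the model. Among the genes called in liver with the same sign at all 6 times, the largest falls were smaller. Cdh1, the epithelial adhesion protein E-cadherin, fell by 1.28 ± 0.12 (adjusted p = 0.00333), although its other kept probe differed by -0.26. Selenbp2, a selenium-binding protein, fell by 1.25 ± 0.15 (adjusted p = 0.00662), and Eif4ebp3, a repressor of translation initiation, fell by 1.12 ± 0.19. Slc39a4, a zinc importer, fell by 0.82 ± 0.13, Rcan2, a calcineurin regulator, fell by 0.72 ± 0.10, Slc13a2, a citrate transporter, fell by 0.67 ± 0.13 and Angptl4, an inhibitor of lipoprotein lipase, fell by 0.65 ± 0.12. Wdr4, Amigo3 and Lrp11 had differences between -0.76 and -0.65, and Serpina9 fell at 6 of 6 times (adjusted p = 0.0202).

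Macrophage markers rose in old liver, with 12 of 15 measured members past the threshold and 14 adjusted over the list alone (median difference 0.73, camera adjusted p = 1.58e-14; adjusted p = 0.179 with an estimated correlation). Lyz2 rose 3.74-fold, the pattern receptor Clec7a 2.40-fold, the scavenger receptor Marco 2.30-fold and Adgre1, the F4/80 antigen, 2.22-fold. Of 5 B and plasma cell markers 4 rose, and 5 adjusted over the list alone (median 1.31, adjusted p = 1.17e-07; adjusted p = 0.179 with an estimated correlation), among them Fcmr at 3.86-fold (detected in 2 of 6 young arrays). Of 6 T and NK cell markers 2 rose, and 5 adjusted over the list alone (median 1.10, adjusted p = 0.000181; adjusted p = 0.241 with an estimated correlation), Cd3g by at least 2.65-fold (detected in 2 of 6 young arrays). The old array at 4 h was the highest in both lymphocyte lists. Its mean was 7.46 for T and NK cells and 6.70 for B and plasma cells, against at most 6.38 and 5.75 in the other old arrays. MHC class II presentation genes had 3 of 7 past the threshold, and 7 adjusted over the list alone (median 0.95, adjusted p = 9.04e-07; adjusted p = 0.261 with an estimated correlation). H2-Eb1 rose 2.06-fold and H2-DMa 1.95-fold. Of 11 interferon response genes 1 rose, Ifi27l2a by 1.93-fold, and 6 adjusted over the list alone (median 0.38, adjusted p = 5.7e-05; adjusted p = 0.261 with an estimated correlation). Red blood cell markers had a median of -0.05 and hepatocyte markers one of 0.00, with 0 of 4 and 0 of 11 past the threshold by limma and camera adjusted p of 0.699 and 0.785.

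Other lists called in liver covered secreted factors, matrix and vessels. Of 7 senescence and secretory genes 3 rose, and 5 adjusted over the list alone (median 0.49, adjusted p = 0.000512; adjusted p = 0.179 with an estimated correlation). These were Cxcl13, the cytokine Il1b at 2.33-fold and the cell cycle inhibitor Cdkn2b at no less than 1.24-fold (detected in 2 of 6 young arrays). Of 10 extracellular matrix genes 1 rose, Dcn by 1.52-fold, with 6 higher and 1 lower adjusted over the list alone (median 0.33, adjusted p = 0.0117; adjusted p = 0.225 with an estimated correlation). Of 8 endothelial markers 2 rose, Cdh5 by 1.32-fold and Emcn by 1.39-fold, and 3 adjusted over the list alone (median 0.21, adjusted p = 0.00193; adjusted p = 0.34 with an estimated correlation). Of 3 nerve and Schwann cell markers 1 rose, Pmp22 by 1.45-fold, and 1 adjusted over the list alone (adjusted p = 0.038; adjusted p = 0.241 with an estimated correlation). Male-biased liver genes had 2 of 11 past the threshold, Cyp4a12b, which fell by 0.86 ± 0.09, and Cyp2d9, which fell by 0.40 ± 0.08, and 6 lower adjusted over the list alone (median -0.28, adjusted p = 0.00101; adjusted p = 0.179 with an estimated correlation). Heat shock and cold-inducible genes had negative differences in 12 of 12 members, 0 past the limma threshold over all genes or adjusted over the list alone (median -0.17, adjusted p = 0.0267; adjusted p = 0.429 with an estimated correlation). The other 18 of 29 lists in liver, which include the clock, bile acid, glucose and lipid synthesis lists, were not called. The female-biased liver genes, the list that holds Cyp2b9, were also among them (5 measured, 3 positive, median 0.03, camera adjusted p = 0.155). Skeletal muscle transcripts were present in some livers, with list means above 8 in young arrays at 4, 8 and 12 h and the old array at 4 h. The age count in liver was 184, 204, 124 or 189 when the arrays of 4, 8, 12 or 16 h were left out, 116 without the 4 arrays with most muscle and with a cosine and sine time term, which alone gave 485, and 181 with muscle content in the model. It was 221 with no filter on dim probes and 1, Cidea (4.69 ± 0.37, adjusted p = 0.0225), with lymphocyte content in the model.

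**Figure D1:**
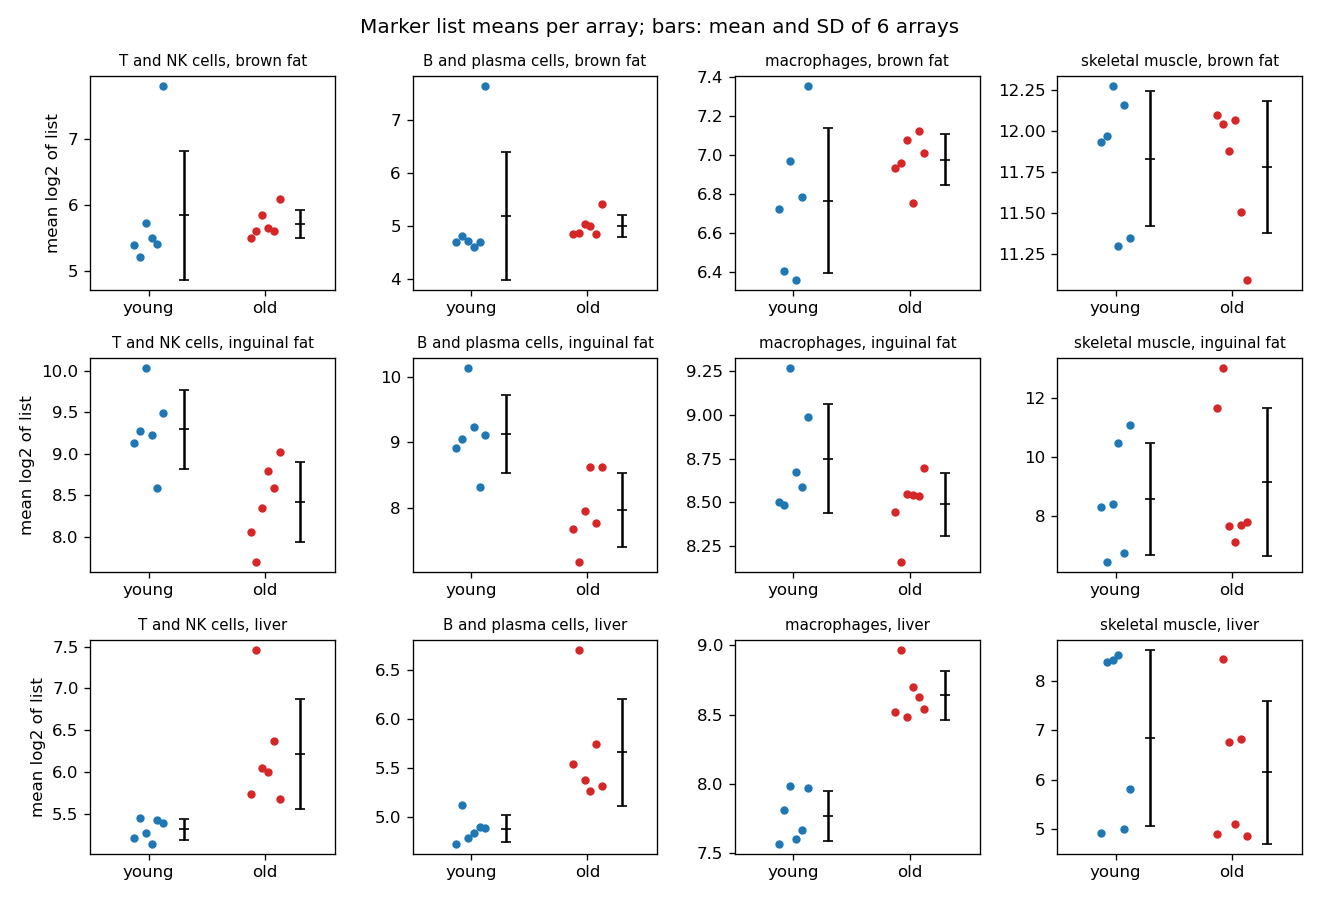
Mean log2 intensity of the T and NK cell, B and plasma cell, macrophage and skeletal muscle marker lists (y axis) in young and old arrays (x axis) of each tissue, 1 point per array, with bars for the mean and SD of 6 arrays. In liver the old macrophage means lie between 8.48 and 8.97 and the young ones between 7.57 and 7.98, while in inguinal fat the muscle means run from 6.46 to 13.03.

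Among genes that rose in inguinal fat the largest changes were those of Krt17, Lgals7 and Gjb2. Krt17, a keratin of hair follicles and skin appendages, rose 14.3-fold (3.84 ± 0.73, 6 of 6 times, adjusted p = 0.0431), Lgals7, a galectin of stratified epithelia, 11.8-fold (3.57 ± 0.76, adjusted p = 0.049; 0.80 to 3.57 over its 3 kept probes) and Gjb2, a gap junction protein, at least 8.10-fold (adjusted p = 0.0435). They were detected in 4, 4 and 3 of 6 young arrays, and Gjb2 in 5 of 6 old ones. Their differences were uneven over the times, from 1.27 to 6.93 for Krt17, 1.01 to 6.43 for Lgals7 and 0.18 to 5.48 for Gjb2. Each was largest at 4 and 12 h. The old arrays of these times also had the highest means of the skin or mammary epithelium list, 8.71 and 9.05. Sfrp5, a secreted Wnt inhibitor, rose 3.21-fold (1.68 ± 0.17, adjusted p = 0.0201) and Mest, an imprinted gene, 3.21-fold (1.68 ± 0.18, adjusted p = 0.0201). The largest fall was in Glycam1, a mucin-like ligand made by high endothelial venules of lymph nodes, which fell by 2.84 ± 0.36 (6 of 6 times, adjusted p = 0.0244). In all, 107 genes rose and 232 fell of 10584 tested, with 2409 at an unadjusted p under 0.05.

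The T cell genes Trbv13-2, Trbv13-1, Cd8b1 and Cd27 had differences between -1.74 and -1.49. The B cell genes Vpreb3, Tnfrsf13c and H2-Ob fell by 1.52 ± 0.26, 1.47 ± 0.29 and 1.46 ± 0.30. The activation marker Cd69 fell by 1.46 ± 0.21 and Ptprcap, a partner of the CD45 phosphatase, fell by 1.47 ± 0.27. Cd8b1 and Cd69 each had another kept probe with a difference of 0.07. Chst3, a sulfotransferase, fell by 1.51 ± 0.27 and Mup6, a major urinary protein, fell by 1.47 ± 0.28. Mup6 and the Trbv13 segments belong to families of similar sequence. Among the rises, Zfp385b was undetected in young inguinal fat and at least 2.54-fold higher in old. Syp, a synaptic vesicle protein, rose 2.89-fold, the nicotinic receptor subunit Chrna5 2.73-fold and the uncharacterised gene 2310011E23Rik 4.39-fold (each detected in 5 of 6 young arrays). Adam3 was detected in 1 of 6 young arrays and rose at least 2.66-fold. Csprs and C130026I21Rik, relatives of Sp100, rose 6.15-fold and 9.09-fold.

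B and plasma cell markers had 3 of 8 members past the threshold, all lower in old inguinal fat, and 8 adjusted over the list alone (median -1.11, camera adjusted p = 1.52e-05; adjusted p = 0.7 with an estimated correlation). Fcrla fell by 1.43 ± 0.28 and Fcmr fell by 1.40 ± 0.27. Of 8 T and NK cell markers 1 fell, Cd3d by -1.42, and 4 adjusted over the list alone (median -0.98, adjusted p = 0.000149; adjusted p = 0.7 with an estimated correlation). MHC class II presentation genes had 0 of 8 past the limma threshold and 7 lower adjusted over the list alone (median -0.56, adjusted p = 0.000149; adjusted p = 0.7 with an estimated correlation); their regulator Ciita differed by -1.19 ± 0.27. Of 11 cell division genes 1 fell, the replication factor Mcm5 by -0.93, and 3 adjusted over the list alone (median -0.42, adjusted p = 0.00171; adjusted p = 0.7 with an estimated correlation). Of 14 macrophage markers Timd4 fell by 0.86 ± 0.11 and Vsig4 rose 1.49-fold, with 3 lower and 1 higher adjusted over the list alone (median -0.27, adjusted p = 0.0405; adjusted p = 0.7 with an estimated correlation).

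Epithelial markers of skin or mammary gland had positive differences in 6 of 6 members, 0 past the limma threshold over all genes and 5 adjusted over the list alone (median 1.40, adjusted p = 0.00171; adjusted p = 0.7 with an estimated correlation). Krt14, a basal keratin, differed by 3.65 ± 1.18 and was higher at 4 of 6 times. Of 14 clock genes Nr1d1, the repressor REV-ERB alpha, rose 2.07-fold (6 of 6 times, adjusted p = 0.0435), with 2 adjusted over the list alone (median 0.20, adjusted p = 0.0219; adjusted p = 0.7 with an estimated correlation). Adipocyte function genes (median 0.30, 11 of 13 positive, adjusted p = 0.0237) and cholesterol synthesis genes (median 0.48, 9 of 12 positive, adjusted p = 0.0462) had 0 members past the limma threshold over all genes or adjusted over the list alone. Both had an adjusted p = 0.7 with an estimated correlation. The other 19 of 28 lists were not called, among them skeletal muscle (median 0.46, adjusted p = 0.456) and endothelium (median 0.10, adjusted p = 0.498). Skeletal muscle means exceeded 10 in the young arrays at 12 and 20 h and in the old arrays at 0 and 4 h. The age count in inguinal fat was 0, 57, 35, 0, 116 or 13 when the arrays of 0, 4, 8, 12, 16 or 20 h were left out, and 1, C130026I21Rik, without the 4 arrays with most muscle and with a cosine and sine time term, which alone gave 355. It was 105 with no filter on dim probes, 512 with muscle content in the model, and 9, all lower and 0 of them among the 339, with lymphocyte content in the model.

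In brown fat 10 genes rose with age and 0 fell of 10506 tested by limma, with 571 at an unadjusted p under 0.05. Ube2ql1, a relative of ubiquitin-conjugating enzymes, rose 7.04-fold (2.82 ± 0.20, 6 of 6 times, adjusted p = 0.000374; detected in 4 of 6 young arrays). Csprs was detected in 1 of 6 young arrays and rose at least 4.30-fold (6 of 6 times, adjusted p = 0.00235). C130026I21Rik was undetected in young brown fat and at least 3.04-fold higher in old (adjusted p = 1.74e-05). Med10, a Mediator subunit, rose 3.08-fold, the potassium channel Kcnj15 3.03-fold and the elastase Cela1 2.59-fold. Ccl12, a chemokine for monocytes detected in 5 of 6 young arrays, rose 2.11-fold, the kinase Ripk4 2.08-fold, Dnajb13, a protein of cilia and flagella, 1.69-fold and Gadd45a, a stress response gene, 1.62-fold. Each of the 10 was higher at 6 of 6 times.

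Shifts of lists were small in brown fat, with 0 members past the limma threshold over all genes. Interferon response genes had 10 of 11 positive differences and 1 higher adjusted over the list alone (median 0.21, camera adjusted p = 0.000323; adjusted p = 0.503 with an estimated correlation), with Irf7 higher by no less than 1.31-fold (detected in 2 of 6 young arrays). Macrophage markers had 10 of 12 positive and 3 higher adjusted over the list alone (median 0.28, adjusted p = 0.000515; adjusted p = 0.54 with an estimated correlation), with Lgals3 at 0.59 ± 0.15. Red blood cell markers had 4 of 4 positive and 3 higher adjusted over the list alone (median 0.49, adjusted p = 0.00104; adjusted p = 0.503 with an estimated correlation), with Slc4a1, the anion exchanger of red cells, at 0.76 ± 0.28. Fatty acid oxidation and PPAR alpha target genes had 2 of 11 positive and 0 adjusted over the list alone (median -0.19, adjusted p = 0.0262; adjusted p = 0.54 with an estimated correlation), with Acot1 at -0.52 ± 0.16. The thermogenesis list (12 measured, median -0.10, adjusted p = 0.365) and the other 23 of 28 lists were not called. The called lists numbered 11 without either array of 20 h and 8 with lymphocyte content in the model, the 4 among them each time. The young array at 20 h held lymphocyte transcripts, with a T and NK list mean of 7.81 against at most 5.74 in the other 5 young arrays. The age count in brown fat was 6, 6, 5 or 6 when the arrays of 0, 4, 8 or 16 h were left out. It was 6 with no filter on dim probes, 6 with probes detected in all arrays and 17 with lymphocyte content in the model.

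Csprs and C130026I21Rik passed the threshold in all 3 tissues, and in liver Csprs rose by 1.65 ± 0.14 (adjusted p = 0.00192) and C130026I21Rik, detected in 1 of 6 young arrays, at least 1.91-fold (adjusted p = 0.0143). Gadd45a and Kcnj15 also rose in both fat depots. Brown and inguinal fat shared 4 called genes with the same direction, where independence would give 0.08 of 9752 genes tested in both. Inguinal fat and liver shared 21 genes lower in old inguinal fat and higher in old liver, against 5.59 under independence, and 8 genes higher in both, against 2.17. The former included the lymphocyte genes Cd79b, Fcmr, Fcrla, Cytip and Trbv13-2. The tissues of 1 age and time were taken to come from the same mice, so these overlaps are not a replication in other animals. Csprs and C130026I21Rik belong to a family of similar sequence, and Sp100 itself differed by -0.90 ± 0.15 in inguinal fat (adjusted p = 0.0336).

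Median, mean and camera direction differed in sign, or 1 of them was 0.00 at 2 decimals, for some lists, 0 of them called. In brown fat these were oxidative phosphorylation, T and NK cells, B and plasma cells and skeletal muscle, and in inguinal fat acute phase, extracellular matrix, male-biased liver genes, glucose metabolism and NAD metabolism and sirtuins. In liver they were thermogenesis (median -0.08, mean 0.58) and adipocyte function (median -0.08, mean 0.33), each with Cidea or Cidec as its 1 called member, cholesterol synthesis and hepatocytes.

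**Figure D2:**
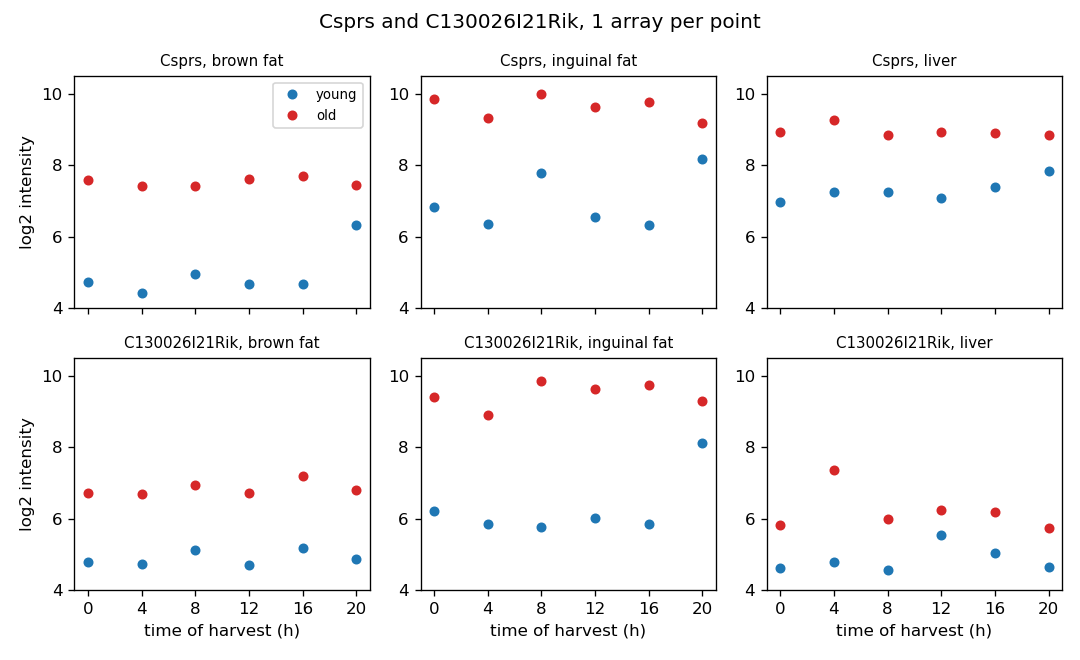
Log2 intensity of Csprs and C130026I21Rik (y axis) by harvest time in hours (x axis) in each tissue, young and old, 1 point per array. The old arrays lie above the young arrays of the same time, and in young inguinal fat the 20 h array is the highest, at 8.16 for Csprs and 8.11 for C130026I21Rik.

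The difference of age effect between tissues was tested directly. Ube2ql1 was the 1 gene whose age effect differed between brown and inguinal fat (difference 2.84 ± 0.20, adjusted p = 0.00392), being 2.82 in brown fat, while in inguinal fat it was detected in 0 of 12 arrays; 2 of 32 splits within times, the real one included, gave at least 1 gene. Between brown fat and liver 84 genes differed, among them Cidea (-4.50 ± 0.19, adjusted p = 1.77e-05), Cidec (-2.91 ± 0.22) and Cxcl13 (-2.32 ± 0.40), all with the larger effect in liver. Cyp2b9 (adjusted p = 0.00168) and Ube2ql1 (adjusted p = 0.000863) also passed, although Cyp2b9 was detected in 0 of 12 brown arrays and Ube2ql1 in 0 of 12 liver arrays. Between inguinal fat and liver 543 genes differed, 420 with the larger value in liver. Cidea differed by -5.00 ± 0.29, Trbv13-2 by -3.71 ± 0.59 and Fcmr by -3.35 ± 0.42, while Krt17, detected in 0 of 12 liver arrays, had an adjusted p = 0.0276. Moxd1, a monooxygenase relative that is male-biased in liver, also passed (adjusted p = 0.0359), at least 1.96-fold higher in old inguinal fat and at least 3.40-fold lower in old liver. It was detected in 1 young and 6 old inguinal arrays and in 3 young and 0 old liver arrays, too few to be tested in liver alone. Of these genes, 0 of 1, 50 of 84 and 402 of 543 passed the detection filter of both tissues. Left-out times moved these counts, to 0 for the 2 fat depots without 0 or 8 h and 4 without 20 h, to 17 to 42 for brown fat and liver without any 1 of the 6, and to 30, 288, 94 or 73 for inguinal fat and liver without 0, 4, 8 or 12 h. With lymphocyte content in the model the 3 counts were 0, 1 and 0, and with no filter on dim probes those with liver were 33 and 212.

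Clock genes had the largest daily rhythms in all 3 tissues. Dbp, a clock output transcription factor, had an amplitude of 1.93 ± 0.13 (log2) in brown fat, 1.86 ± 0.13 in inguinal fat and 2.35 ± 0.21 in liver, and peaked at 9.36, 9.88 and 8.86 h after the first harvest. Its peak to trough ratio was 14.5-fold, 13.1-fold and 25.9-fold (adjusted p = 0.000101, 0.000681 and 0.00086). Arntl, which encodes the activator BMAL1, peaked in the opposite part of the day, at 22, 22.5 and 21 h, with amplitudes of 1.45 ± 0.12, 1.31 ± 0.12 and 1.81 ± 0.17. Nr1d1 peaked at 5.09, 6.55 and 6.03 h with amplitudes of 1.45 ± 0.13, 1.59 ± 0.18 and 2.19 ± 0.12. These fits used 12 arrays per tissue, with both ages together.

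Of 14 measured clock genes 8 were rhythmic in brown fat, 3 in inguinal fat and 12 in liver, and 11, 10 and 13 adjusted over the list alone. The clock repressor gene Ciart had amplitudes of 1.47 ± 0.11 in brown fat and 2.32 ± 0.15 in liver. Per2, a core repressor, peaked at 13.1 h in brown fat (adjusted p = 0.00448) and 12.9 h in liver (adjusted p = 0.0184). Per3 in liver had an amplitude of 1.26 ± 0.12 and the deubiquitinase gene Usp2 one of 1.76 ± 0.16. Over all genes 36 were rhythmic in brown fat, 13 in inguinal fat and 358 in liver, with 1180, 566 and 2037 at an unadjusted p under 0.05. The 8 genes Arntl, Cdkn1a, Dbp, Dtx4, Lonrf3, Nr1d1, Slc5a6 and Tspan4 were called in all 3 tissues. Of these, Cdkn1a, which encodes the cell cycle inhibitor p21, had amplitudes of 0.71, 0.96 and 1.61 and peaked at 20.6, 22.1 and 20.1 h.

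Further rhythmic genes of large amplitude follow by tissue, with no test of rhythm between tissues. In brown fat E2f2, a cell cycle transcription factor, had an amplitude of 1.23 ± 0.12, the thyrotropin receptor gene Tshr one of 1.03 ± 0.12 and Mycl one of 0.93 ± 0.15. In inguinal fat Osgin1, also called in brown fat, had an amplitude of 1.18 ± 0.14 and Mest one of 0.94 ± 0.12. In liver the elongase gene Elovl3 (1.41 ± 0.13), the choline kinase gene Chka (1.29 ± 0.11) and Hectd2os (1.28 ± 0.19) were among the largest. Of 358 rhythmic genes in liver, 114 peaked between 20 and 24 h and 21 between 0 and 4 h. Testing 6 separate time levels in place of a 24 h wave gave 7, 2 and 36 genes, and leaving out 1 array gave 15 to 46, 1 to 19 and 166 to 372. The count moved by over 1.5 times without the young array at 8 h or old arrays at 8, 12 or 20 h in brown fat, any array but the young one at 8 h in inguinal fat, and young arrays from 4 to 20 h or old arrays at 8, 12 or 20 h in liver. Without the arrays with most muscle the count was 0 in inguinal fat and 31 in liver, with muscle content in the model 125 in liver, with no filter on dim probes 1 in inguinal fat, and with trend and robust settings 595 in liver.

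**Figure D3:**
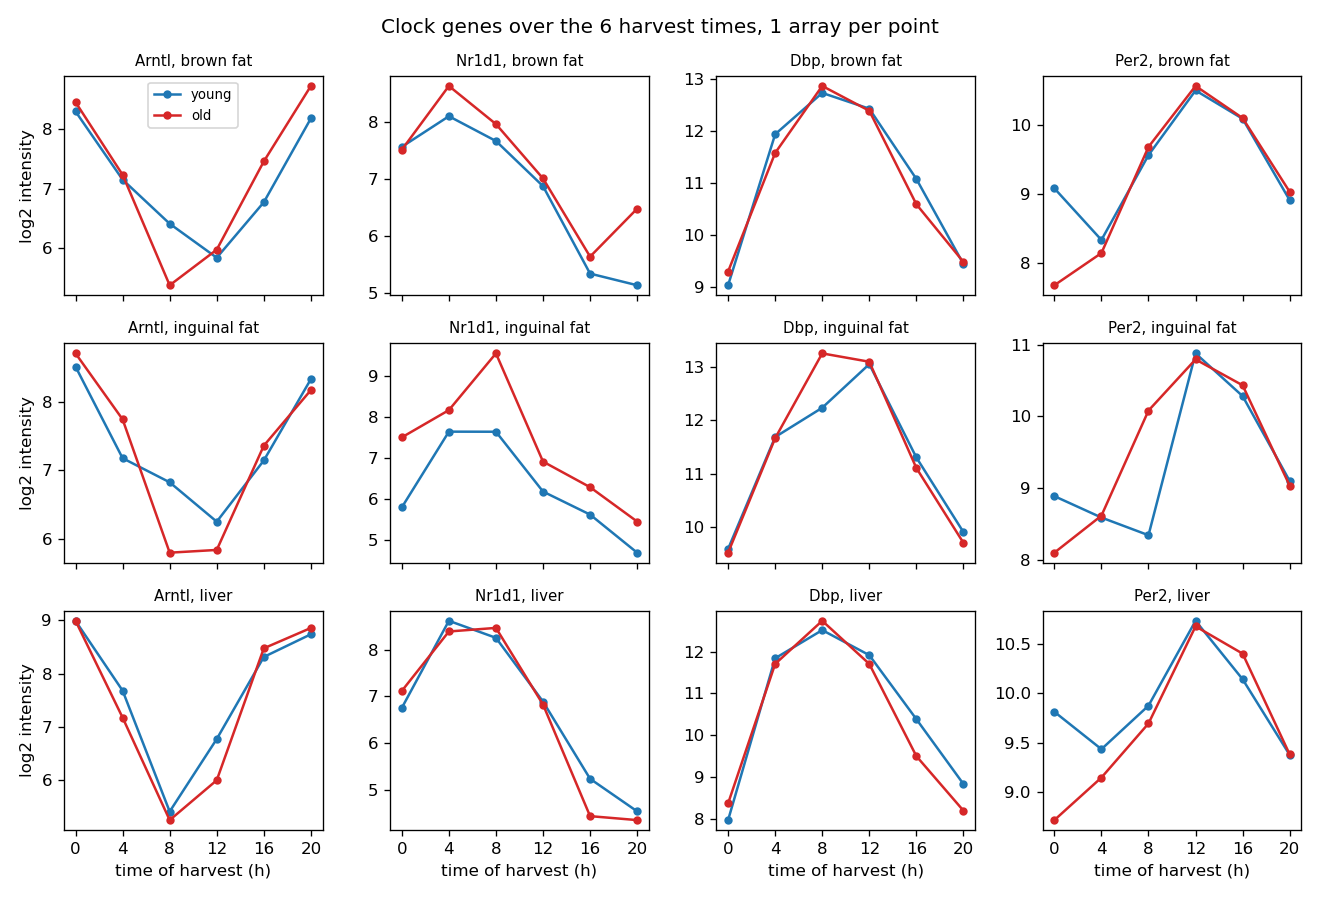
Log2 intensity of Arntl, Nr1d1, Dbp and Per2 (y axis) at the 6 harvest times in hours (x axis) in each tissue, young and old, 1 point per array joined by lines. In all 3 tissues and both ages Arntl is lowest, and Dbp highest, at 8 or 12 h.

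Few genes had a rhythm that differed by age past the threshold, all in brown fat, where chance is not excluded. Siglech, a receptor of plasmacytoid dendritic cells, peaked at 15.2 h in young and 1.50 h in old brown fat, with amplitudes of 0.99 and 0.90 (adjusted p = 0.0455). Map2k1, the kinase MEK1, peaked at 12.0 h in young and near 0.06 h in old brown fat (adjusted p = 0.0497). The cochaperone gene Hscb, Gm5069 and Morf4l1b also passed, each with an adjusted p = 0.0497, and their peaks differed by between -12 and -11.4 h. These 5 genes were the count in brown fat, which 2 of 32 splits within times, the real one included, reached, and limma called 0 in inguinal fat and 0 in liver, with 557, 692 and 971 genes at an unadjusted p under 0.05. The genes with the smallest p elsewhere were Slc3a2 in inguinal fat (adjusted p = 0.318), followed by ND4L, Kpna3, Gabarapl2 and Atp5a1, and Cyp2c40 in liver (adjusted p = 0.0553), followed by Iqub, Yipf5, Klf5 and Cd300a. In each tissue 0 of 14 clock genes passed in limma, over all genes or adjusted over the list alone, with the smallest adjusted p at 0.0947 over the list for Arntl and Bhlhe40 in brown fat. The count in brown fat was 4 without the young array at 0 h, 0 of them among the 5, 35 without the young array at 8 h, 1 without the old array at 8 h and 0 without the young arrays at 4, 12, 16 or 20 h or the old arrays at 0, 4, 12, 16 or 20 h, while inguinal fat gave 6 without the old array at 8 h and liver 7 and 1 without the old arrays at 4 and 16 h. In brown fat it was 0 with muscle content in the model or low values floored, 1 with no filter, 3 with probe means, 10 with trend and robust settings and 21 with lymphocyte content in the model, and the last 2 gave 10 and 31 in liver.

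The mean amplitude of the 14 clock genes was 0.848 in young and 0.896 in old brown fat, a difference of 0.05 (SD over genes 0.221; exact permutation p = 0.594; larger in old for 7 of 14 genes). In inguinal fat it was 0.775 in young and 0.963 in old, a difference of 0.19 (SD 0.28, exact permutation p = 0.531, larger in 12 of 14). In liver it was 1.11 in young and 1.28 in old, a difference of 0.17 (SD 0.216, exact permutation p = 0.0625, larger in 10 of 14). The smallest p that these swaps allow is 0.0312. Among the rhythmic clock genes the median shift of the peak was -0.51 h in brown fat, -0.36 h in inguinal fat and -0.21 h in liver. The shifts ran from -1.24 to 1.15 h over 8 genes, -0.48 to 0.05 h over 3 and -0.97 to 1.06 h over 12. In old arrays 7, 2 and 8 of these genes peaked earlier and 1, 1 and 4 later. The shifts were not tested as a set, and harvests were 4 h apart. In brown fat the amplitude difference was -0.01 without the young array at 0 h and -0.03 without the young array at 8 h. Without 1 array it ranged from 0.08 to 0.29 in inguinal fat and from 0.10 to 0.24 in liver.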

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

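The tests on endothelial, red blood cell and adipocyte genes and on the old liver array at 4 h were chosen only after the results were seen; the lymph node test and the counts over other splits were planned.

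Lymphocyte transcripts were lower in old inguinal fat, where the T, NK, B and plasma lists together had a median difference of -1.11 (quartiles -1.31 and -0.76, 16 genes). A lower share of all cells other than adipocytes would lower endothelial markers too, but the lower quartile of that list was -0.05, which argues against it. Less lymph node tissue in the old samples remains open and may account for the pattern: 5 genes of lymph node stroma and follicles (Ccl19, Ccl21a, Cxcl13, Cr2 and Fcer2a; Cxcl13 also stands in the senescence list) had a median of -1.08, although 0 of them passed limma's threshold (adjusted p 0.0579 to 0.132). Cr2 and Fcer2a are also expressed by B cells, while the stromal Ccl19 (mean log2 level 10.8 in inguinal fat) and Ccl21a differed by -1.08 and -1.28. Outside this list, Glycam1, made by high endothelial venules of lymph nodes, differed by -2.84 and passed limma's threshold (adjusted p = 0.0244). An age difference in lymphocytes within the tissue or its node also stays open and was not tested.

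Macrophage and lymphocyte transcripts were higher in old liver, where the macrophage, T, NK, B and plasma lists together had a median difference of 1.07 (quartiles 0.69 and 1.30, 26 genes). More blood in the old samples would raise red cell genes, whose upper quartile was -0.03, which argues against it. Without the old array at 4 h the median was 0.96, but 15 of the 26 genes are macrophage markers, so this is a weak test of lymphoid tissue. The lymphocyte lists were higher in every old array than in any young one. Their means were at least 5.68 against at most 5.44 for T and NK cells, and at least 5.27 against at most 5.13 for B and plasma cells. These values argue against lymphoid tissue in the old array at 4 h alone as the whole cause. An age difference in resident or entering immune cells, and small amounts of lymphoid tissue in several old samples, remain open.

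Cidea and Cidec were higher in old liver by 4.51 and 2.79. Fat attached to the old samples would raise other adipocyte genes, but the upper quartile of the adipocyte function list without Cidec was 0.13 (7 genes, median -0.12), which argues against it as the whole cause. An age difference in liver cells stays open and was not tested.

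Some arrays stood far from the other 5 of their group. This held for 7 of 60 groups of marker lists and 7 of 116 groups of named genes, where chance gives about 1 in 20 for replicates. The 6 arrays of a group are 6 harvest times, so an effect of time can also set an array apart. In young brown fat at 20 h the list means were 7.81 for T and NK cells and 7.64 for B and plasma cells (next highest 5.74 and 4.80), and Csprs was at 6.33 (next 4.96). In old brown fat at 20 h the B and plasma mean was 5.41. In old liver at 4 h the B and plasma mean was 6.70, the nerve and Schwann cell mean 6.06, Ccl5 11.08 and H2-M2 9.77. In young brown fat the epithelium mean at 8 h was 6.86, the red blood cell mean at 4 h was 7.73 and Cela1 at 4 h was 6.27. C130026I21Rik was at 8.11 in young inguinal fat at 20 h, Tmem45b at 6.72 in young liver at 12 h and Wdr4 at 5.48 in young liver at 8 h.

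Age effects differed between tissues, by a direct test, for 1 gene between brown and inguinal fat, 84 between brown fat and liver and 543 between inguinal fat and liver. Only 0, 50 and 402 of these genes passed the detection filter of both tissues. Of the 32 splits that part the ages at every time, 2 gave at least 1 gene for the fat depots, the real one and a split with 115, so chance is not excluded there, and the latter points to a structure of the samples; what that split follows was not tested. For brown fat and liver 1 of 32 splits, the real one, gave as many (highest other 0), and for inguinal fat and liver also 1 of 32 (highest other 3). Rhythm differed by age for 5 genes in brown fat, where 2 of 32 splits, the real one and a split with 6, gave as many, so chance is not excluded. For inguinal fat and liver, with 0 genes each, 32 of 32 splits give as many whatever the data, so chance was not tested there. The highest others were 3 and, in liver, 113. These rhythm splits keep the age differences of the genes, and swapping the ages at some times can turn such a difference into one of rhythm. The high count in liver therefore does not show a structure of the samples. For the same reason the split with 6 in brown fat is an imperfect measure of chance.

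Probes with no named gene, outside the main comparisons, also differed by age by limma: 16 of 3059 in brown fat (16 higher), 64 of 2970 in inguinal fat (51 lower) and 107 of 3174 in liver (97 higher).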

How the results depend on the processing

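Offset 50, floored low values, cyclic loess, muscle and lymphocyte content as covariates and removal of the arrays with most muscle were chosen after the data were seen; the others were planned. No background correction, median scaling and the beadchip block were not run, since the scanner table could not be tied to samples. Except where a construction is named, the cause was not tested.

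Genes differing by age in brown fat (10) were 6 with no filter, 6 with detection in all arrays, 17 with the lymphocyte covariate and 5 to 13 without 1 array. In inguinal fat (339) they were 105 with no filter, 512 with the muscle covariate, 9 with the lymphocyte covariate, 1 without the arrays with most muscle and 0 to 116 without 1 array. In liver (395) they were 221 with no filter, 181 and 1 with the muscle and lymphocyte covariates, 116 without the arrays with most muscle and 124 to 313 without 1 array. Removal of the arrays with most muscle also replaced the 6 time levels with cosine and sine in the age fits, which alone gave 355 in inguinal fat and 485 in liver. Leaving out arrays leaves fewer samples, and no filter tests more genes; in inguinal fat and liver the lymphocyte covariate itself differed by age, so it removes part of the age term there. Under it Glycam1 in inguinal fat went from -2.84 to -1.38 and H2-M2 in liver reversed, to -0.175.

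Rhythmic genes with 6 time levels were 7 in brown fat (36), 2 in inguinal fat (13) and 36 in liver (358). Without 1 array they were 15 to 46, 1 to 19 and 166 to 372. In inguinal fat they were 1 with no filter and 0 without the arrays with most muscle, and in liver 595 with trend and robust eBayes, 125 with the muscle covariate and 31 without the arrays with most muscle. Genes whose rhythm differed by age in brown fat (5) were 0 with floored values, 1 with no filter, 3 with probe means, 10 with trend and robust eBayes, 0 with the muscle covariate, 21 with the lymphocyte covariate and 0 to 35 without 1 array. In inguinal fat (0) they were 0 to 6 without 1 array. In liver (0) they were 1 with offset 50, 2 with cyclic loess, 10 with trend and robust eBayes, 2 with the muscle covariate, 31 with the lymphocyte covariate and 0 to 7 without 1 array. The clock amplitude difference in brown fat (0.048) was -0.013 and -0.028 without the young arrays at 0 and 8 h, and ranged from -0.028 to 0.085 without 1 array, against 0.083 to 0.288 in inguinal fat (0.188) and 0.098 to 0.244 in liver (0.174).

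Lists called with an estimated correlation were 0 in each tissue (main 4, 9 and 11). With the lymphocyte covariate they were 8 in brown fat and 3 in inguinal fat, and without 1 array 3 to 11 in brown fat. Genes whose age difference differed between brown and inguinal fat (1) were 0 with detection in all arrays, 2 with trend and robust eBayes, 2 and 0 with the muscle and lymphocyte covariates and 0 to 4 without 1 array. Between brown fat and liver (84) they were 33 with no filter, 38 with detection in all arrays, 34 and 1 with the muscle and lymphocyte covariates and 17 to 42 without 1 array. Between inguinal fat and liver (543) they were 212 with no filter, 0 with the lymphocyte covariate and 30 to 427 without 1 array.

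With no replicate block, that is without pairing by time, genes differing by age were 11, 477 and 408 in brown fat, inguinal fat and liver, and the differences between tissues 4, 58 and 596. The count for the fat depots (8827) stayed within 1.5 times of its value under every alternative run. Of the named age genes, H2-M2 in liver is the 1 that changed direction under any alternative run. With the lymphocyte covariate 0 of 24 kept their call in inguinal fat and 1 of 24 in liver, against 10 of 10 in brown fat. With no filter, weak signal and the larger number of genes tested were not separated.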

Other observations

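The test of neighbouring genes in brown fat was chosen only after the result was seen; those in the other tissues and the counts over splits were planned.

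Csprs and C130026I21Rik were intermediate in the young inguinal fat array at 20 h, with intensities of 270.0 and 261.0, against at most 202.7 and 58.4 in the other 5 young arrays and at least 560.0 and 468.7 in the old ones. Young brown fat at 20 h held Csprs at 64.9, against at most 13.9 in the other young arrays, while C130026I21Rik there was 11, within the range of the others. Young liver at 20 h held Csprs at 214.7, against at most 152.9 in the other young arrays. C130026I21Rik there was 4.4, also within the range of the others. Ube2ql1 and Med10, which lie next to each other, both rose in brown fat, from between 16.6 and 71.4 to between 168.0 and 526.8 for Ube2ql1 and from between 306.1 and 545.0 to between 1235.9 and 1610.9 for Med10. Med10 did not pass in inguinal fat (-0.20 ± 0.12, adjusted p = 0.36) or liver (0.06 ± 0.09, adjusted p = 0.793), and Ube2ql1 was detected in 0 of 12 arrays of either.

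A hypothesis was that the young and old animals differ genetically at some loci, which would place called genes near each other. Pairs of called genes that moved the same way within 5 tested genes of each other numbered 1 in brown fat, the pair Ube2ql1 and Med10, against a mean of 0.04 over 10000 random draws (share with as many 0.0414). There were 63 in inguinal fat (mean 30.04) and 87 in liver (mean 53.96), each with a share of 1e-04, the smallest the draws can give. The counts in inguinal fat and liver exceed those of random draws, as the hypothesis predicted, while the pair in brown fat prompted its own test and is no evidence either way. Families of genes that lie together and are expressed in the same cells, such as Gimap6 and Gimap7 or Trbv13-1 and Trbv13-2, give the same excess. The test therefore does not separate these sources and decides nothing about the hypothesis. Gimap7 and Cd53, which stood in such pairs in inguinal fat and in liver, had opposite signs there (-1.07 and 1.30, -1.10 and 1.21).

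Other splits of the arrays tested whether chance gives as many genes. Of 462 splits of 12 arrays into 6 and 6, 452 could be fitted and 100 were drawn. In brown fat 2 of 100 gave at least the real 10 genes, the real one and a split with 55, several times the real count, which points to a structure of the samples besides age. In inguinal fat 1 of 100, the real one, gave 339 or more (highest other 41), and in liver 1 of 100 gave 395 or more (highest other 44). Among the 32 splits that swap ages within times, 1 gave as many in each tissue, the highest others being 2 in brown fat, 0 in inguinal fat and 4 in liver. By these swaps within times chance is excluded at 0.05 for the counts, 1 of 32 being the smallest share they can give. Which arrays shared a beadchip could not be told, so the swaps do not separate age from a beadchip difference between the groups. The 100 splits are a weaker measure. Where both arrays of a time fall in 1 group, that time adds nothing to their contrast, which lowers their counts. Neither test covers the dependence on single arrays, and in inguinal fat the count was 0 to 116 without 1 array. For rhythm, 1 of 100 orders of the times gave as many as the real 36, 13 and 358 genes, with highest others of 5, 2 and 11, which excludes chance there as well.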
